A study of Mus musculus with 5 samples.

How the data were processed

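Gene expression was measured in CD4 T cells of C57BL/6 mice that had been cultured in 5 ways, with 1 array for each culture. The arrays were 1-colour Agilent whole-genome mouse arrays, on which Cy3-labelled RNA binds to short DNA probes. There were no replicates, so no test, p-value or spread between samples could be had, and every comparison is between single arrays. The number of arrays limits the precision. All 5 arrays lay on 1 slide and had 1 scan time and 1 extraction time, so neither separates the groups.

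The authors deposited the scanner output of each array, per the file headers from Agilent Feature Extraction 10.7.1.1, the version that the submitters' processing notes also name. Its processed signal is a linear intensity that the software had subtracted the background from and corrected for trends across the array, per the file headers, with no scaling between arrays. The series' deposited value table also holds an intensity. Set against the scanner values, each of its columns was the processed signal divided by 1 constant: between 99.7% and 99.8% of probes lay within 0.01 log2 units of that ratio. Its scale and direction are therefore known, and it has no centring per gene. The 75th percentile of each column was 1.00. The column medians were 0.0762 for Th1, 0.103 for Th1+TGFb, 0.123 for rested, 0.0693 for Th1reg and 0.0925 for iTreg. How the authors chose the constants is not given in the sources used here. That table served only as an alternative.

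Each array held 62976 spots, of which 59305 were not controls, for 55681 probes. Control spots were left out, as were the 109 to 142 spots per array that the software had marked as outliers. No spot was saturated. The processed signal was averaged over the spots of a probe, and the main value was log2 of that average minus log2 of the array's own 75th percentile. Probes were named through their RefSeq accession in a gene table of assembly GRCm38.p6, which matched 28331 of the 55681 probes to 21368 genes, of which 21366 had a value on all 5 arrays; the other probes were not used. The array design names the older build mm9, so the table was used for names only and no coordinates are given. Of the genes, 5754 had several probes, and the probe with the highest mean signal stood for the gene. The other probes of a gene called 2-fold apart went the same way in 87.7% to 92.5% of cases, depending on the comparison, and were themselves 2-fold apart the same way in 58.9% to 70.7%.

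A probe whose signal the software did not mark as well above background was given the higher of its own signal and the lowest signal among probes well above background on that array. A difference against such a value is a lower bound and is written as at least N-fold. Where the lower signal was well above background but near that lowest signal, the fold is imprecise. Where the dim array's value lay above the other array's signal, no direction could be had and the difference was set to 0. Genes dim on both arrays were left out of a comparison. A gene was counted as higher or lower when its log2 difference was at least 1, which is 2-fold. Repeat spots on the same array give the technical spread: the median SD over probes with repeat spots was 0.0549 to 0.0709 log2 units, and was 0.151 to 0.184 where the signal was under 100. The largest resulting SD of a difference was 0.10 over all such probes and 0.26 where the signal was under 100. This spread excludes spots marked as outliers and holds nothing of the variation between cultures.

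The 7 comparisons, the 23 gene lists and the rule for named genes were fixed before the data were examined. The named genes were Foxp3, Tbx21, Ifng, Il10, Ctla4 and Il2ra in every comparison. Added to them were the 6 largest differences each way among genes well above background on both arrays and the 4 largest bounds each way. Each list that stood apart, or had at least 3 members 2-fold apart, gave the 4 members with the largest differences. Predicted genes, Y-linked genes and Xist were left out of the size ranking. The text names a part of the genes the rule gives. A list was set against 10000 random lists of the same size, matched on mean signal in 20 bins, and is said to stand apart when its median lay outside the central 95% of their medians. Lists with fewer than 5 measured members got no percentile. This percentile describes these arrays and is no test of the cultures. The lists were T cell identity, regulatory T cell (Treg) signature, Th1 programme, Th2, Th17, follicular helper (Tfh), TGF-beta response, T cell activation, quiescence and lymphoid homing, cell cycle, cytotoxic effector, type I interferon response, interferon-gamma-inducible, inhibitory receptors, IL-2 and STAT5 targets, glycolysis, sterol synthesis, stress and apoptosis, chemokine receptors and integrins, and markers of B, myeloid, CD8 T and NK, and erythroid cells. List members with no matched probe were Itgae, Ly6c2, Mx1, Mx2, Hspa1b, Ighm, Trdc, Hbb-bs and Ahsp.

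Of the alternatives, 10 were planned. They were normexp background correction, quantile normalization, cyclic loess, scaling to the median of probes detected on all arrays, a filter on both arrays, no filter and no floor, no floor, the median of all probes of a gene, the deposited value table, and random lists not matched on signal. The normexp alternative used the median spot signal with an offset of 50, since no mean signal was among the columns available for it. After the data were seen, 2 further scalings were added. The 75th percentile of probes detected on all arrays was added because between 45.7% and 48.7% of spots per array were well above background. The other used the 8 spike-in probes, out of 10, that were well above background on every array. Spike-ins are control RNAs added in set amounts.

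The procedures were tested on simulated data. In a comparison of the Th1 array with itself over 12239 genes, with noise from the repeat spots, 200 genes were shifted. Of those shifted 2.5-fold, 189 were called, as were 190 of those shifted 4-fold and 3 of those shifted 1.5-fold. No unshifted gene was called at any of these sizes, which noise so small against the 2-fold threshold made near certain. The simulation held no difference between arrays or cultures, so it does not give the rate of false calls between real arrays. For rested against Th1 over 13228 genes, 9 of 200 random lists of 20 genes stood apart with no shift, and 199 did so with a shift of 1.5 log2 units. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.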

Results

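The expression of 21366 genes was measured in 5 cultures that started from naive CD4 T cells of mouse spleen. Th1 cells had been stimulated for 4 days through CD3 and CD28 with IL-2 and IL-12 while IL-4 was blocked. iTreg cells came from the same kind of naive cells after 4 days of that stimulation with IL-2 and TGF-beta, with IFN-gamma and IL-4 blocked. The other 3 cultures began as Th1 cells. One went straight into the iTreg medium for 4 more days (Th1+TGFb, 8 days in all). Another was rested for 4 days in IL-2 with both cytokines blocked and no CD3 or CD28 stimulation (rested, 8 days). The last passed from rest into the iTreg medium for 4 days (Th1reg, 12 days). The labels give the purpose only as the profiling of CD4 T cells under different culture conditions. Each group had 1 array and there were no replicates, so the values below describe single arrays. Between 45.7% (Th1) and 48.7% (iTreg) of the spots were well above background, and the 75th percentile of signal was 240 for Th1, 198 for Th1+TGFb, 144 for rested, 307 for Th1reg and 271 for iTreg.

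Foxp3, the transcription factor that defines Treg cells, was well above background only on the Th1reg and iTreg arrays, with scaled log2 signals of 4.12 and 5.26. On the Th1, Th1+TGFb and rested arrays it was not well above background. Tbx21, which encodes the Th1 transcription factor T-bet, had a scaled signal of 6.42 in Th1, 4.71 in Th1+TGFb, 4.22 in rested, 4.86 in Th1reg and 0.58 in iTreg. Ifng, the main Th1 cytokine, stood at 10.23 in Th1, 9.56 in Th1+TGFb, 2.79 in rested, 8.37 in Th1reg and 1.27 in iTreg. The cytokine gene Il10 was measured at 1.67 in Th1 and 2.03 in Th1+TGFb and was not well above background on the other 3 arrays.

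**Figure D1:**
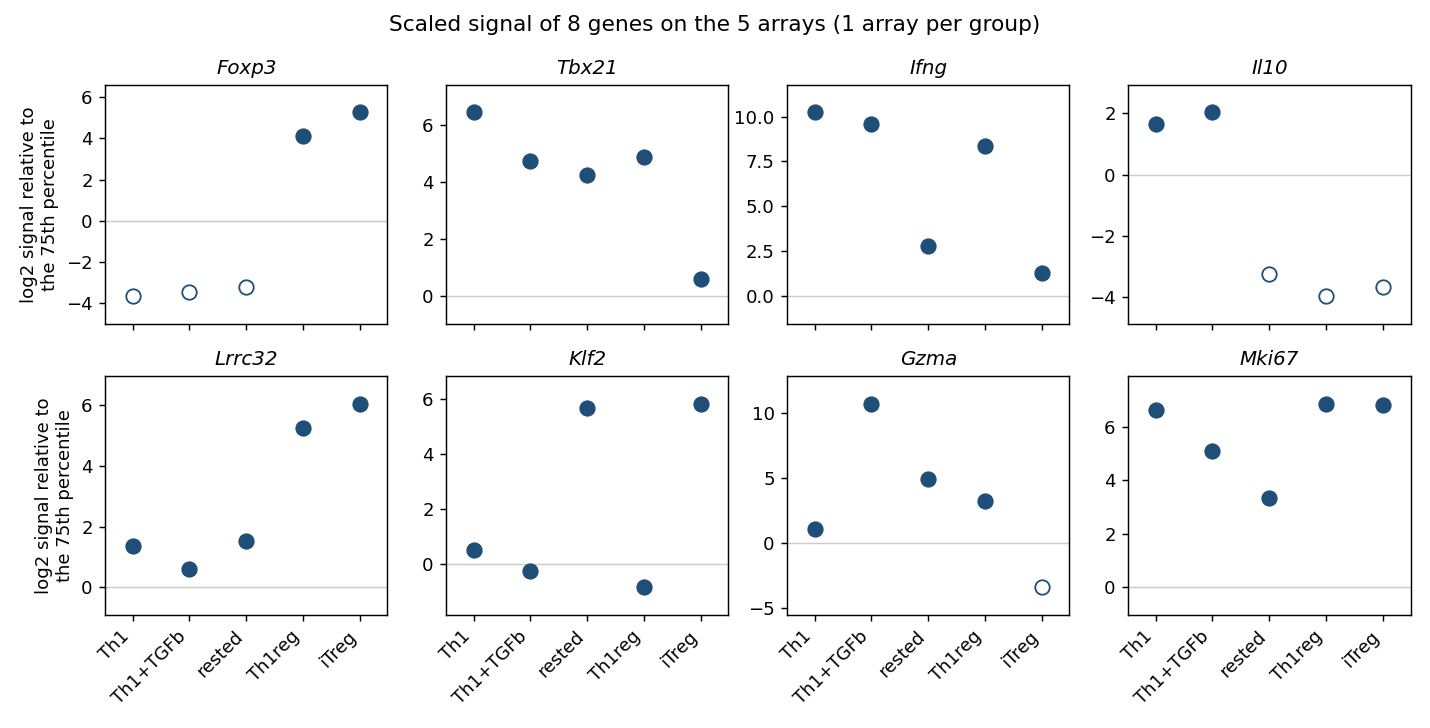
Each panel plots 1 gene's log2 signal relative to the array's 75th percentile on the 5 arrays, with filled circles for probes well above background and open circles for those not. Foxp3 is filled only in Th1reg (4.12) and iTreg (5.26), while Ifng is high in Th1 (10.23), Th1+TGFb (9.56) and Th1reg (8.37).

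The first comparison asked how naive cells differed after the iTreg and the Th1 culture. Foxp3 was at least 482-fold higher in iTreg than in Th1, and the Treg genes Nt5e and Lrrc32 were 57.2-fold and 26.2-fold higher. Ifng was 498-fold lower in iTreg, Tbx21 57.2-fold lower and Gzmb, encoding granzyme B, 301-fold lower. Ctla4 was 4.45-fold lower in iTreg, Il10 at least 40.1-fold lower, and Il2ra differed by 0.22 log2 units. Besides those of Ifng and Gzmb, the largest differences among genes well above background on both arrays included Drc1, 378-fold higher, Atp1b1, 286-fold higher, and Pdlim4, 200-fold higher in iTreg, and Plac8, 1060-fold lower, Tgm2, 611-fold lower, and Serpinf1, 456-fold lower.

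Of 24 measured Th1 programme genes, 15 were at least 2-fold lower in iTreg than in Th1 and 2 were higher, with a median log2 difference of -2.36, below all 10000 random lists. Ly6c1 was 142-fold lower and Ccl5 had a log2 difference of -6.57. Among 18 cytotoxic genes 13 were lower (median -2.50), as were 16 of 19 glycolysis genes (median -1.74), among them the glucose transporter Slc2a3 (14.1-fold) and hexokinase Hk2 (14.2-fold). T cell activation genes (median -1.31), interferon-gamma-inducible genes (-0.87), type I interferon genes (-1.02), sterol synthesis (-1.05), stress and apoptosis (-1.49), inhibitory receptors (-0.93), Th2 genes (-0.92) and T cell identity (-1.25) also stood apart as lower. Lag3, an inhibitory receptor gene, was 49.1-fold lower. In the other direction stood the quiescence and homing list, with 7 of 24 genes higher and 3 lower (median 0.50). Klf2 was 39.9-fold and Klf3 35.6-fold higher, both linked to the resting state of naive T cells, while Satb1 was 11.3-fold and Il7r 5.51-fold lower. The TGF-beta response list was higher too (median 0.86), with the receptor Tgfbr1 14.6-fold higher, although Tgfb3 was at least 190-fold lower. The Treg signature had 10 of 23 genes higher and 8 lower, and its median of 0.22 lay just above the central 95% of random lists, which ended at 0.09. All 9 measured Th17 genes were 2-fold apart, 4 higher and 5 lower. Ccr6 was 15.8-fold higher and Ahr 9.35-fold higher, whereas Il21 was at least 466-fold lower. The direction of the Th17 median, -1.25, turned to 3.23 over genes well above background on both arrays. Of 6 markers of CD8 T and NK cells, 3 were higher and 2 lower: Cd8a was at least 10.4-fold and Klri2 at least 4.65-fold higher in iTreg, and Klra8 at least 20.2-fold lower. The medians of T cell identity, Th2, T cell activation and the Treg signature each lay within the range of random lists under at least 1 other processing choice.

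Over all genes, 1420 of 13151 were at least 2-fold higher in iTreg and 2325 were lower. The split depended on scaling: 37.9% of the 2-fold genes were higher in the main setting, 64.5% with the 75th percentile of detected probes, 58.4% with spike-ins and 25.6% with normexp. The median of all genes moved by 0.37 log2 units with detected probes and by 0.28 with spike-ins.

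Rest without receptor stimulation was examined by setting rested cells against the Th1 cells they came from. These cultures also differed in IL-12, the block of IFN-gamma and the days of culture, which were not separated from rest. Genes of proliferation and activation were much lower in rested cells: 28 of 29 cell cycle genes were at least 2-fold lower and none higher (median -3.30), among them Bub1, 18.8-fold, and Plk1, 15.3-fold, which act in mitosis. All 19 measured sterol synthesis genes were lower (median -3.01), with Fdps 16.8-fold and Cyp51 13.0-fold lower. T cell activation genes had 13 of 19 members lower (median -2.96), including the early response gene Nr4a1, 154-fold. Ifng was 174-fold lower and Ccl4, a chemokine gene, 217-fold lower. The glycolysis list (15 of 19 lower, median -1.78), the IL-2 and STAT5 targets (13 of 16 lower, median -1.57) and the Treg signature (14 of 22 lower, median -1.50) lay on the same side. The inhibitory receptors did so as well (median -1.57), with Lag3 57.7-fold lower. Among 24 Th1 programme genes 13 were lower and 5 higher (median -1.49). Tbx21 was 4.58-fold lower, while the chemokine receptor gene Cxcr3 was 36.5-fold higher.

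Quiescence and homing genes were higher in rested cells in 15 of 24 cases (median 1.71, above all random lists). Klf2 was 35.8-fold higher, Klf3 24.0-fold and Tcf7 14.0-fold. Among genes well above background on both arrays, Ifi203 was the furthest above Th1 (268-fold), followed by Rtp4 (85.6-fold), Ifi208 (63.1-fold) and the phosphodiesterase gene Pde2a (61.7-fold). Ifi203 and Ifi208 belong to a family of similar genes, so the signal of each is uncertain. Type I interferon genes had a median of 0.87 and chemokine receptors and integrins one of 0.82, and both stood above random lists, but spike-in scaling turned these medians to -0.30 and -0.35, and over genes well above background on both arrays the chemokine receptor median was -0.02. Marker genes of other cells also differed: the B cell list had a median of 1.95 with 4 of 7 genes higher, among them Ms4a1 (3.87-fold), and the myeloid list 1.36 with 5 of 9 genes higher, among them Siglech (2.72-fold). The myeloid genes Lyz2, Lyz1, S100a8 and S100a9 were not well above background on any array. Siglech, Csf3r and Itgam were well above background on all 5 arrays, and whether their probes report RNA of myeloid cells was not tested. Spike-in scaling moves all genes of this comparison by -1.16 log2 units, bounds apart. It takes Siglech, Csf3r and Ms4a1 to less than 2-fold apart, while Itgam stays above 2-fold. The medians of these B cell and myeloid lists, of inhibitory receptors and of the Th1 programme lay within the range of random lists under at least 1 other processing choice.

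In this comparison 2322 of 13228 genes were higher in rested and 3518 lower, so 39.8% of the 2-fold genes were higher. That share was 65.4% with the 75th percentile of detected probes, 52.6% with the median of detected probes, 49.9% with no filter and no floor, 24.2% with normexp and 6.49% with spike-ins, which moved the median of all genes by -1.16 log2 units. The rested array was the dimmest, and relative to spike-ins its median signal over the 21015 probes detected on all arrays was 2.67-fold lower than that of Th1.

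Moving Th1 cells straight into the iTreg medium was compared with the Th1 starting point. Granzyme and killer-cell receptor genes were much higher in Th1+TGFb: Gzma was 818-fold higher, Gzmg 164-fold, Gzme 152-fold and Gzmd at least 299-fold. Gzmc to Gzmg are near-identical copies, so the signal of each is uncertain. Of 19 cytotoxic genes 14 were higher and none lower (median 1.999, above all random lists). The receptor genes Klra5 (67.7-fold) and Klre1 (9.24-fold) and the secreted proteoglycan gene Esm1 (130-fold) were also higher. The list of CD8 T and NK cell markers stood apart with a median of 2.23, while Cd8a was not well above background on either array and Cd8b1 differed by -0.17 log2 units, both named after their values were seen. Foxp3 was not well above background on either array. Of the 4 Treg signature genes furthest apart, Nt5e was 20.9-fold, Ebi3 4.89-fold and Entpd1 4.65-fold higher in Th1+TGFb, while Icos was 3.20-fold lower. Ifng differed by -0.66 log2 units, Il10 by 0.36 and Ctla4 by -0.14, and Tbx21 was 3.26-fold lower. Il2ra was 2.03-fold lower.

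The Th1 programme was higher in 12 of 24 genes (median 0.98), with the chemokine genes Xcl1 26.9-fold and Ccl5 10.9-fold higher. TGF-beta response genes stood apart as higher (median 0.64, 5 of 16 higher and 2 lower). Pmepa1 and Skil, both feedback regulators of that pathway, were 4.39-fold and 2.58-fold higher. Th17 genes (median 0.97) included Ahr, 11.4-fold higher. Th2 genes had a median of 0.83, with Gata3 4.23-fold higher. Chemokine receptors and integrins were higher in 9 of 19 cases (median 0.84), with Cxcr6 42.3-fold and Itga4 19.8-fold higher. Cell cycle genes were lower in 21 of 29 cases (median -1.16). T cell identity (median 0.06), quiescence and homing (0.10) and type I interferon genes (0.32) stood above random lists, but spike-in scaling turned their medians to -0.30, -0.26 and -0.04, and normexp turned that of T cell identity to -0.04. The myeloid list had a median of 0.94 and the B cell list 1.31. The medians of T cell identity, quiescence, Th2, Th17 and the B cell list lay within the range of random lists under at least 1 other processing choice. There were 1483 genes higher and 1011 lower of 13057, so that 59.5% of the 2-fold genes were higher, against 78.7% with the 75th percentile of detected probes, 73.3% with the median of detected probes, 43.3% with normexp and 24.3% with spike-ins, which moved the median of all genes by -0.37 log2 units.

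The same medium was then followed from the rested state, in Th1reg against rested cells. Foxp3 was at least 163-fold higher in Th1reg, Ccr8, a chemokine receptor of Treg cells, at least 61.5-fold higher, and Lrrc32 13.3-fold higher. The Treg signature had 14 of 23 genes higher and 2 lower (median 2.22, above all random lists). This list shares members with the T cell activation list, among them Tnfrsf9 and Icos. It was also lower in rested cells than in Th1, so a return of genes that had fallen was not separated from a gain. Ifng was 47.8-fold higher, while Tbx21 differed by 0.63 log2 units, Ctla4 by 0.91, and Il2ra was 7.23-fold higher. Il10 was not well above background on either array. Activation genes were among the largest differences, with Nr4a1 233-fold and Egr2 108-fold higher, next to the phosphatase gene Dusp4 (117-fold) and the chemokine and cytokine genes Ccl4 (184-fold) and Csf2 (132-fold).

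All 29 measured cell cycle genes were at least 2-fold higher in Th1reg than in rested cells (median 3.53), as were all 19 sterol synthesis genes (median 2.86), and 13 of 20 T cell activation genes were higher with 2 lower (median 2.86). TGF-beta response genes had a median of 1.09, with Pmepa1 24.8-fold and Skil 7.26-fold higher. Quiescence and homing genes were lower in 21 of 24 cases and higher in none (median -2.79). Klf2 was 92.1-fold lower and Tcf7 30.3-fold lower. The neuropeptide receptor gene Vipr1 was 743-fold lower and Pde2a 167-fold lower. Type I interferon genes were lower in 14 of 21 cases (median -1.58), with Rtp4 17.4-fold lower. Chemokine receptors and integrins (median -1.41), the Th1 programme (median -0.25, 9 higher and 9 lower of 23) and the interferon-gamma-inducible list (median -0.33) stood below random lists, but with spike-ins their medians were 0.06, 1.16 and 1.15. The myeloid list had a median of -1.44. Of 7 B cell markers 6 were lower, with Cd22 6.50-fold, Cr2 5.84-fold and Ms4a1 at least 6.41-fold lower, and their median of -1.71 lay within the central 95% of random lists. The medians of the myeloid list, the Th1 programme and the TGF-beta response lay within the range of random lists under at least 1 other processing choice. Of 13331 genes 3678 were higher and 2667 lower. The higher genes made up 58.0% of the 2-fold genes, against 36.4% with the 75th percentile of detected probes, 47.1% with the median of detected probes, 70.2% with normexp and 92.9% with spike-ins, which moved the median of all genes by 1.47 log2 units.

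**Figure D2:**
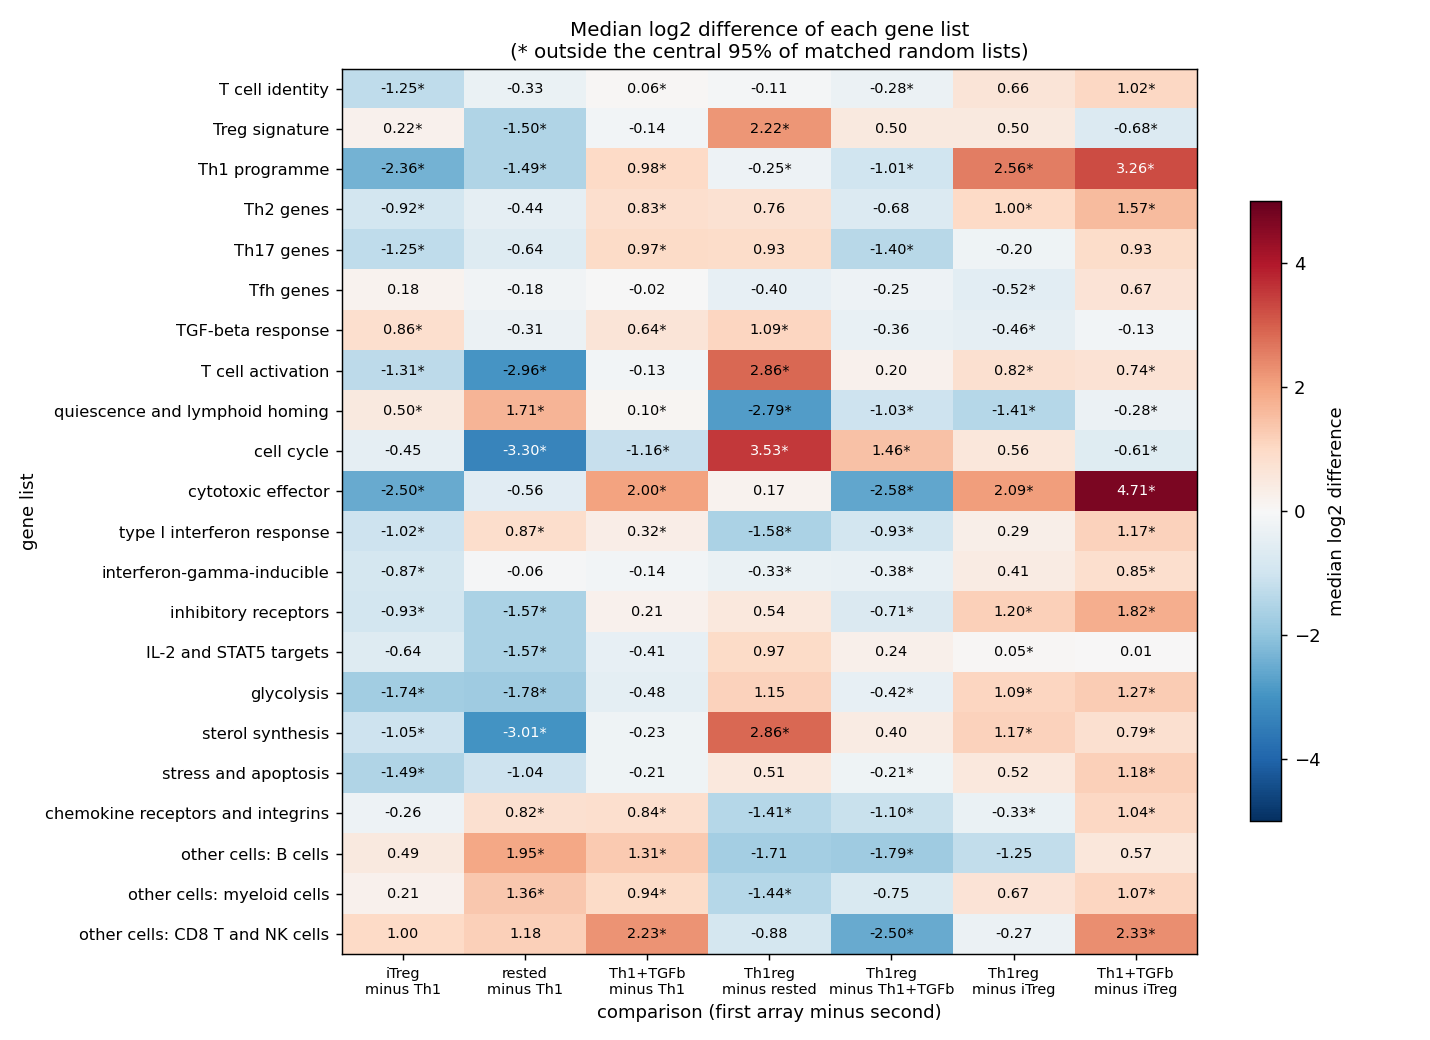
The heat map gives the median log2 difference of each gene list with at least 5 measured members in every comparison, first array minus second, with red for higher and blue for lower and an asterisk where the median lay outside the central 95% of matched random lists. The cell cycle list is -3.30 in rested minus Th1 and 3.53 in Th1reg minus rested, and the cytotoxic list is 1.999 in Th1+TGFb minus Th1 and -2.58 in Th1reg minus Th1+TGFb.

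Th1reg, which was rested before the iTreg medium, was set against Th1+TGFb, which went into the same medium without rest. Th1reg had also been cultured for 12 days in all and Th1+TGFb for 8, so rest was not separated from the added days. Foxp3 was at least 189-fold higher in Th1reg, Lrrc32 25.1-fold and Ccr8 7.74-fold higher. The imprinted RNA gene H19 was 26.0-fold higher and the cytokine gene Lta 18.0-fold higher. Over the whole Treg signature 6 of 23 genes were higher and 3 lower, and its median of 0.50 lay within the central 95% of random lists. Il10 was at least 63.8-fold lower in Th1reg, Ifng 2.29-fold lower, and Tbx21 differed by 0.14 log2 units.

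Cytotoxic genes were lower in Th1reg than in Th1+TGFb in 14 of 19 cases and higher in none (median -2.58): Gzma was 185-fold lower, Gzmb 17.4-fold, Gzme 1595-fold and Prf1, which encodes perforin, 5.99-fold. The CD8 T and NK marker list had a median of -2.50. Il21 was 268-fold lower and the chemokine receptor gene Cxcr1 262-fold lower. Their Th1reg signals of -3.02 and -3.78 lay near that array's lowest signal well above background, -3.96, so these folds are imprecise. The Th1 programme was lower in 12 of 24 genes and higher in 3 (median -1.01), with Ccl5 106-fold and Havcr2 at least 42.7-fold lower. Inhibitory receptors (median -0.71), type I interferon genes (median -0.93), Th17 genes (median -1.40), chemokine receptors and integrins (median -1.10) and the quiescence and homing list (median -1.03) also stood below random lists. Cell cycle genes were higher in 24 of 29 cases (median 1.46). The glycolysis list (median -0.42), the interferon-gamma-inducible list (-0.38), the stress and apoptosis list (-0.21) and the T cell identity list (-0.28) stood apart too, but spike-in scaling turned them to 0.25, 0.29, 0.46 and 0.40, and those of stress and of T cell identity lay within the range of random lists under at least 1 other processing choice. The B cell list had a median of -1.79. The myeloid list's median of -0.75 lay within the central 95% of random lists, with Itgam 5.13-fold, Csf3r 2.63-fold and Siglech 2.46-fold lower. There were 1615 genes higher and 2002 lower of 13213, with 44.7% of them higher, against 27.4% with the 75th percentile of detected probes, 31.1% with the median of detected probes, 58.7% with normexp and 84.2% with spike-ins, which moved the median of all genes by 0.67 log2 units. Over the 414 genes at least 8-fold apart between Th1 and rested, the array labelled Th1reg lay nearer Th1 (median position 0.991, with rested at 0 and Th1 at 1) than the array labelled Th1+TGFb (0.707), so the directions between these arrays assume that their labels are right.

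Th1reg was set against iTreg to compare the cultures in which Foxp3 was well above background. Foxp3 was 2.20-fold lower in Th1reg. Ifng was 137-fold higher in Th1reg and Tbx21 19.4-fold higher. Il2ra differed by -0.32 log2 units, Ctla4 was 2.47-fold higher, and Il10 was not well above background on either array. Th1 programme genes were higher in 17 of 23 cases and lower in 1 (median 2.56, above all random lists), with Csf2 46.9-fold, Cxcr3 29.6-fold and Ccl3 21.6-fold higher. Cytotoxic genes were higher in 11 of 16 cases (median 2.09), among them Nkg7, 34.6-fold, and Gzmb, 16.9-fold. The Treg signature, with 8 of 22 genes higher and 4 lower, had a median of 0.50 that lay within the central 95% of random lists. Tigit was at least 15.4-fold higher and Nrp1 4.98-fold lower.

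Sterol synthesis (15 of 20 higher, median 1.17), glycolysis (10 of 19 higher, median 1.09), T cell activation (median 0.82) and inhibitory receptors (median 1.20) stood above random lists in Th1reg. The quiescence and homing list was lower in 16 of 24 cases (median -1.41), with Klf2 103-fold and Klf3 69.6-fold lower, next to Atp1b1 (338-fold) and Pdlim4 (204-fold). Lower medians were found for the TGF-beta response (-0.46), Tfh genes (-0.52, with Bcl6 12.2-fold lower) and chemokine receptors and integrins (-0.33). Th2 genes had a median of 0.998, which over genes well above background on both arrays was -0.14. IL-2 and STAT5 targets stood below random lists with a median of 0.05, which was -0.35 with quantile normalization, -0.36 with cyclic loess, -0.08 with the median and -0.31 with the 75th percentile of detected probes. The medians of these targets, the TGF-beta response, Tfh genes and inhibitory receptors lay within the range of random lists under at least 1 other processing choice. The erythroid list had 3 measured genes, all lower, including Hba-a2 (4.53-fold). Of 7 B cell markers 4 were lower and 1 higher, with Cd79b 3.54-fold and Ms4a1 at least 4.55-fold lower, and their median of -1.25 lay within the central 95% of random lists. Cd8a was well above background only on the iTreg array, a log2 difference of -3.33 or further below 0. Of 13183 genes 2066 were higher and 1597 lower, or 56.4% of the 2-fold genes higher, against 31.0% with the 75th percentile of detected probes and 73.4% with normexp.

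The last comparison set Th1+TGFb against iTreg, which both ended in the iTreg medium. Foxp3 was at least 415-fold lower in Th1+TGFb and Lrrc32 43.7-fold lower, and the Treg signature had 11 of 23 genes lower and 9 higher (median -0.68). Ifng was 314-fold higher, Tbx21 17.5-fold, Il10 at least 51.4-fold, and Gzmb 294-fold higher. Ctla4 was 4.04-fold higher and Il2ra 2.35-fold lower. The Th1 programme was higher in 21 of 24 genes (median 3.26) and the cytotoxic list in 16 of 19 (median 4.71). Ccl5 was 1037-fold higher and Plac8 2325-fold higher, while Klf2 was 67.7-fold lower and H19 180-fold lower. Inhibitory receptors (median 1.82), Th2 genes (1.57), glycolysis (1.27), stress and apoptosis (1.18), type I interferon genes (1.17), chemokine receptors and integrins (1.04), T cell identity (1.02), interferon-gamma-inducible genes (0.85), sterol synthesis (0.79) and T cell activation (0.74) stood apart as higher. The quiescence and homing list stood below random lists (median -0.28). Cell cycle genes were lower in 8 of 29 cases (median -0.61). The CD8 T and NK markers had a median of 2.33 and the myeloid list one of 1.07. Against the direction of its list, Cd8a was at least 8.89-fold lower in Th1+TGFb, and the B cell gene Cd79b was at least 9.13-fold lower. The medians of the quiescence list and of both these marker lists lay within the range of random lists under at least 1 other processing choice. There were 2159 genes higher and 1404 lower of 13271. Of these 60.6% were higher, against 50.2% with the 75th percentile of detected probes and 21.0% with spike-ins, which moved the median of all genes by -0.65 log2 units.

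**Figure D3:**
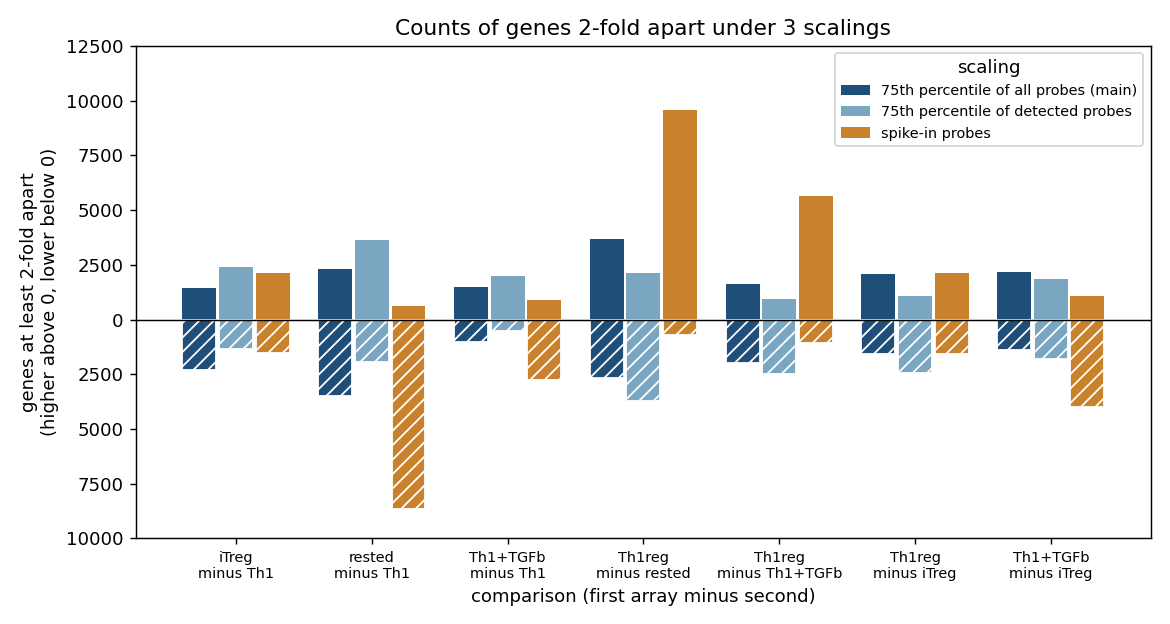
Bars give the number of genes at least 2-fold higher (solid, above 0) and lower (hatched, below 0) in the first array than in the second, for the main scaling, the 75th percentile of detected probes and the spike-in probes. In rested minus Th1 the counts are 2322 higher and 3518 lower in the main scaling, and 600 higher and 8644 lower with spike-ins.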

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

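All tests in this part were chosen only after the result was seen, except that of a label swap.

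Entry into the iTreg medium was seen from 2 starting states, Th1 cells that were still activated (Th1+TGFb minus Th1) and rested cells (Th1reg minus rested), and 6 gene lists that stood apart in both had medians of opposite sign. With 1 array per group the difference was not tested, and it assumes that the labels of the Th1+TGFb and Th1reg arrays are right. The cell cycle median was -1.16 from Th1 and 3.53 from rest, opposite under all settings. The myeloid marker median was 0.94 from Th1 and -1.44 from rest. With spike-ins these were 0.58 and -0.097, the latter so close to 0 that the opposite signs rest on a bound set to 0. The medians were 0.98 and -0.25 for the Th1 programme, 0.10 and -2.79 for quiescence and homing, 0.32 and -1.58 for type I interferon genes, and 0.84 and -1.41 for chemokine receptors and integrins. Spike-in scaling gave both medians of each of these last 4 lists the same sign, which follows from the 1 constant it adds to all genes of a comparison, bounds apart (-0.37 from Th1 and 1.47 from rest). Relative to random lists, which the constant moves too, all 6 lists still stood above them in one comparison and below them in the other. Not all did so under every other setting: the Th1 programme from rest lost this with unmatched random lists (-0.25) and quantile normalization (-0.34), quiescence from Th1 with unmatched random lists (0.10), and the myeloid list from rest with cyclic loess (-0.85). From rest the Th1 programme also had as many genes at least 2-fold higher as lower, and Ifng was 47.8-fold higher. Its median there does not show a fall of the whole programme. Over 10894 genes the differences of the 2 comparisons, which share no array, had a Pearson r of -0.43 and a Spearman rho of -0.49. This is not particular to them: over the 8 pairs of comparisons that share no array r lay between -0.51 and 0.16. These are correlations across genes, and genes are not independent replicates. The 2 comparisons also subtract different starting arrays. In the main setting, for each of the 6 lists but the Th1 programme, the median of rested minus Th1 had the sign opposite to that of Th1reg minus rested. For those lists, part of the difference between the 2 comparisons is thus the difference between their starting arrays. The starting state that the design names stays open as an explanation and was not tested.

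Granzymes and killer-cell receptors were higher in Th1+TGFb than in Th1. CD8 T cells in the Th1+TGFb culture would bring Cd8a and Cd8b1, but 0 of these 2 genes were well above background and at least 2-fold higher. NK cells would bring Tyrobp, Fcer1g, Ncr1 and Klrb1c, and 0 of these 4 genes were. Signal shared between near-identical granzyme probes could inflate the list, but without Gzmc to Gzmg the median of its other 14 genes was 1.31, above all random lists. Shared signal between probes of the killer-cell receptor genes was not tested. The added culture days and medium that the design names stay open and were not tested.

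In rested cells, cell cycle and sterol genes were lower and quiescence genes higher than in Th1. The rested array was the dimmest, which could give a difference that depends on intensity, yet after cyclic loess the cell cycle median was still -2.58. A single factor for the whole array, such as less labelled RNA, moves all genes alike, whereas the quiescence median lay 5.02 log2 units above the cell cycle median. This value restates the pattern, since 1 factor cannot give lists that move apart, and it argues against the factor only as the whole cause. Such a factor is not excluded as an addition to the pattern, and how much RNA each cell held was not measured. Rest itself, which the design names, stays open as untested. The rested culture also differed from Th1 in IL-12, the block of IFN-gamma and added culture days, which were not separated from it.

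Foxp3 was not well above background in Th1+TGFb and was bright in Th1reg, although both ended in the iTreg medium. RNA from cells that had no TGF-beta was examined with the TGF-beta response list. Its median was 0.64 in Th1+TGFb minus Th1 and lay above random lists in 13 of 13 settings, all of the same 2 arrays. Those arrays also differ in culture days, IL-12 and the block of IFN-gamma, so the list cannot decide this. A swap of the labels of these 2 arrays may also give the pattern, and the test written before its result was seen went with it: over 414 genes the Th1+TGFb array lay 0.71 and the Th1reg array 0.99 of the way from rested to Th1, a difference of -0.28 (-0.39 to -0.26 over the settings). Cell cycle genes, whose median was 1.46 higher in Th1reg than in Th1+TGFb, are among those far apart between Th1 and rested. All 414 genes were chosen by their difference between stimulated Th1 cells and rested cells without stimulation. Stimulation after rest could thus move that position too, which was not tested, so the position cannot tell a swap from such stimulation. Over genes 8-fold higher in Th1 than in iTreg the Th1+TGFb array lay nearer Th1 (0.927) than Th1reg (0.589). A swap and RNA from cells without TGF-beta therefore stay open. So does the rest period that the design names, with its added culture days, which was not tested.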

How the results depend on the processing

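The scalings to the 75th percentile of detected probes and to spike-ins were chosen after seeing the data; the other alternatives were planned. Of 154 counts of 2-fold genes under the alternatives 115 lay within 1.5 times the main count and 39 did not. Of 95 list medians that stood apart, 67 did so under every alternative that left the list at least 5 measured members. With signal required on both arrays, 92 of the 95 had that many. Of 7325 values of named genes under the alternatives, 3881 moved by more than the technical spread of 0.10 log2 units and 3441 did not. The other 3 were reversed, so the folds depend on the processing. Only genes at least 2-fold apart in the main setting could be called reversed, and smaller differences that changed sign were counted in the first 2 groups. The cause was not tested for any value below except where the setting's own construction shows it. The median of all genes moved by -0.17 to 0.22 log2 units with quantile normalization, -0.20 to 0.19 with cyclic loess, -0.26 to 0.25 with the median of detected probes, -0.43 to 0.46 with their 75th percentile, -1.16 to 1.47 with spike-ins, and up to 0.11 with the deposited value table. A scaling by 1 constant per array moves random lists as well, so the scalings to detected probes and to spike-ins can turn a median's sign but ended no list's standing apart. Signal over background limits the dim genes, whose differences are bounds.

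With normexp the counts of higher genes were 616 in iTreg against Th1, 1060 in rested against Th1 and 576 in Th1+TGFb against Th1. The counts of lower genes were 1572 in Th1reg against rested, 1032 against Th1+TGFb and 635 against iTreg, and 896 in Th1+TGFb against iTreg. With the median of detected probes 655 genes were lower in Th1+TGFb than in Th1 and 1074 higher in Th1reg than in Th1+TGFb. Requiring signal on both arrays, which leaves fewer genes, gave 1631 genes lower in Th1reg than in rested, 1242 than in Th1+TGFb and 996 than in iTreg. With no filter and no floor, which adds dim genes, 2324 were higher in iTreg, 3944 in rested and 2636 in Th1+TGFb than in Th1, and 3295 in Th1+TGFb than in iTreg. In that setting 4408 were lower in Th1reg than in rested, 3373 than in Th1+TGFb and 2652 than in iTreg.

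With the 75th percentile of detected probes 2415 genes were higher and 1332 lower in iTreg than in Th1, 3649 and 1930 in rested than in Th1, and 1090 and 2430 in Th1reg than in iTreg. There 533 were lower in Th1+TGFb than in Th1, and 2124 were higher in Th1reg than in rested and 946 than in Th1+TGFb. With spike-ins 1517 genes were lower in iTreg than in Th1. Higher and lower counts were then 600 and 8644 in rested against Th1, 891 and 2773 in Th1+TGFb against Th1, and 9554 and 727 in Th1reg against rested. They were 5625 and 1054 in Th1reg against Th1+TGFb, and 1059 and 3996 in Th1+TGFb against iTreg.

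With the median of all probes of a gene Il1rl1 was reversed to -0.31 in Th1reg minus iTreg and Itgam to -0.032 in Th1+TGFb minus iTreg. With spike-ins Cd28 was reversed to 0.11 in Th1reg minus rested. The Th17 median in iTreg minus Th1 was reversed to 3.23 with signal required on both arrays and was 0.0042, within random lists, with no filter and no floor.

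The following medians no longer stood apart. Against random lists not matched on signal these were the Treg signature in iTreg minus Th1 (0.22), T cell identity (0.063) and quiescence (0.10) in Th1+TGFb minus Th1, and the Th1 programme in Th1reg minus rested (-0.25). In the same setting they were T cell identity (-0.28) and stress (-0.21) in Th1reg minus Th1+TGFb, IL-2 and STAT5 targets in Th1reg minus iTreg (0.052), and quiescence in Th1+TGFb minus iTreg (-0.28). With normexp they were Th2 genes in iTreg minus Th1 (-0.53), inhibitory receptors in rested minus Th1 (-0.80), and the TGF-beta response in Th1reg minus rested (0.11) and minus iTreg (-0.20). Normexp also ended those of T cell identity (-0.076) and stress (-0.035) in Th1reg minus Th1+TGFb and of quiescence in Th1+TGFb minus iTreg (-0.33). With quantile normalization they were the Th1 programme in Th1reg minus rested (-0.34), T cell identity in Th1reg minus Th1+TGFb (-0.075) and the TGF-beta response in Th1reg minus iTreg (-0.31). With cyclic loess they were the myeloid list in rested minus Th1 (0.61) and Th1reg minus rested (-0.85) and the TGF-beta response in Th1reg minus iTreg (-0.42).

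With signal required on both arrays they were Th2 genes (-0.88) and T cell activation (-0.75) in iTreg minus Th1, and the Th1 programme (-0.87), chemokine receptors (-0.018) and B cell markers (1.32) in rested minus Th1. That setting also ended those of the TGF-beta response in Th1reg minus rested (1.14), stress in Th1reg minus Th1+TGFb (-0.13), and Th2 genes (-0.14) and inhibitory receptors (0.57) in Th1reg minus iTreg. With no filter and no floor they were B cell markers in rested minus Th1 (0.69), Th2 genes (0.51), Th17 genes (0.26) and B cell markers (0.32) in Th1+TGFb minus Th1, Tfh genes in Th1reg minus iTreg (-0.24), and myeloid (0.54) and CD8 T and NK markers (0.64) in Th1+TGFb minus iTreg. With the median of all probes they were T cell identity (-0.77) and T cell activation (-0.20) in iTreg minus Th1, B cell markers in rested minus Th1 (1.34) and in Th1+TGFb minus Th1 (0.98), and the myeloid list in Th1+TGFb minus iTreg (0.49).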

Other observations

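In this part the tests of both hypotheses were written before their results were seen, and the shared genes named are those with the widest gap.

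Between Th1reg and iTreg, 20 genes were at least 4-fold above all 3 other arrays in both. Those with the widest gap were Foxp3 (at least 163-fold), Stxbp6 (at least 31.5-fold), Nav1, Drc1 and Lrrc32, the last encoding a protein that holds latent TGF-beta on the Treg surface. Apol9b, Apol9a, H19, Actr3b and Ccr8 came next. A programme that Th1reg and iTreg share beyond their last culture step may be read from this number, which lies above the median of 9.5 over the 10 pairs of arrays. The pair ranked 4 of 10, behind Th1 with Th1+TGFb (57 genes), Th1+TGFb with Th1reg (24) and rested with iTreg (22), and over the settings it had 11 to 53 genes and ranks from 1 to 5. The test is thus weak. By their definition the 20 genes were at least 4-fold lower in Th1+TGFb, which ended in the same medium, so that gap is no test of the medium. If the Th1+TGFb array held RNA of cells without TGF-beta, which stays open above, the medium could account for them. A response to the medium that depends on the starting cells was not separated from such a programme either.

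A further hypothesis was that Th1reg cells keep part of the Th1-over-iTreg difference. Over 208 genes at least 8-fold higher in Th1 than in iTreg, with iTreg at 0 and Th1 at 1, the median position of Th1reg was 0.589 (0.513 to 0.621 over the settings). It was 0.400 for rested (0.063 to 0.481) and 0.927 for Th1+TGFb (0.823 to 0.968). Over 72 genes 8-fold higher in iTreg, the Th1reg position was 0.541 (0.541 to 0.770 over the settings), against 0.626 for rested (0.496 to 0.896) and 0.805 for Th1+TGFb (0.795 to 0.936). Here the order of Th1reg and rested turned under some settings, among them quantile normalization (0.682 and 0.659). These positions do not show that the difference was kept: Th1reg lay nearer Th1 than the rested cells did over the 208 genes, and Ifng stood at 2.79 in rested and 8.37 in Th1reg, so part of it may have come back after rest. Keeping and regaining were not separated, an array not used to choose the genes tends to lie between those that were, and a label swap with Th1+TGFb would change which position is which.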
